A study of Mus musculus with 12 samples.

How the data were processed

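The series holds 12 arrays of total RNA from mouse ES cells, undifferentiated or after 3 days in retinoic acid, with 3 biological samples per group and 2 technical arrays per sample, per the labels. RNA was amplified once and labelled with Cy3, so each array has 1 colour. The deposited scanner tables give, per the file headers, the net mean intensity of each spot on a linear scale, which means that the authors' software had already taken off the local background; the method of doing so is not given in the sources used here. No value was below 0, and the tables hold no local background, detection or saturation flag, slide or scan date. Each scanner file has 41268 spot rows, 41174 of them probes with one row each and 94 control rows. In the header of the file of undifferentiated replicate 2, technical array 2, the array is named as the other technical array of that sample, and its values differ from that array's.

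The authors also deposited a set of processed intensity for 41173 of these probes. The submitters' processing notes name R 2.15.0 and limma. Each column held the same order of probes as its scanner table (rank correlation 1) and a median of 56.9, and correlated at 0.999997 to 0.999998 with the quantile-normalized values on the log2 scale, so it is a linear, uncentred, quantile-normalized version of the same arrays. It served as an alternative.

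Probes were named through the accessions the tables give, matched without versions to the RefSeq gene table of assembly GRCm38.p6. The accession named 27479 probes, the symbol in the file 5478, an older symbol 671, the file's own name 1279 and the description 1 (Nanog), and 6266 had no name. The array's genome build is not given in the sources used here, so no coordinates are printed, and the RefSeq table served only for names and for which genes are neighbours. The 21179 named genes were each represented by the probe with the highest mean log2 intensity over all arrays.

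Intensities were quantile-normalized between the 12 arrays, 50 was added, and log2 was taken, so that fold changes of dim genes are understated. A probe counted as above background when it exceeded the 95th percentile of the 27 negative control spots of its array, and a gene was tested when this held on at least 4 of the 6 arrays of either group, which left 15326 genes. For 142 of the called genes no array of one group was above this limit. For such a gene a named fold is a lower bound ("at least"): the brighter group's mean against the mean of, per array, the higher of the lowest signal above the limit and the gene's own signal, without the added value. Of the genes tested, 230 exceeded an intensity of 40000 on some array, close to the brightest spots (42952 to 49949), and 23 of these were called.

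The technical arrays of each sample were averaged, and the 3 retinoic acid samples were compared with the 3 undifferentiated samples with limma 3.58.1 (lmFit and eBayes, two-sided, in R 4.3.3), without covariates and with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The 22 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists. Also computed were the p with an estimated correlation, under which the pluripotency call held and the calls of the other 7 lists did not, and fry, which tests whether the genes of a list move on balance one way. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

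The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The named genes were the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap (leaving out accessions, clones and predicted genes), up to 3 called members of each list in either direction, and 21 genes chosen in advance. Some genes that this rule names are counted in the totals but are not reported here by name. Other list members and gene families are named after their values were seen. The plan foresaw another scanner format, with the 75th percentile as the scaling, and its fallback for other scanners was used. The set of negative control spots, the added 50 and the naming of Nanog from its description were chosen after the data were examined. Alternatives planned and run were scaling to the 75th percentile or the median, no filter or a filter on all 12 arrays, the mean of a gene's probes or each probe by itself, either technical array alone, all 12 arrays with the sample as a random block, the replicate number as a block, a variance trend with robust estimation, the authors' values, an adjusted p under 0.01, and each sample left out in turn. Chosen after the data were examined were 1 or 10 in place of the added 50, the array with the doubtful header left out, and the second brightest probe.

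The fit was tested on simulated data for this comparison: normal values with the means and SDs of the 15326 genes, and 200 genes changed by known sizes in each of 20 runs. It recovered 0.895% of genes changed by 0.5, 35.2% of those changed by 1 and 80.8% of those changed by 2 on the log2 scale, and 3.9% of the calls were false. In the data far more genes were called (2872 higher and 2083 lower). The Benjamini-Hochberg cut-off is looser where more genes change, so these recovered shares do not carry over to the real comparison. A list shifted by 1 on average was called in 20 of 20 runs and an unshifted list in 1 of 20. The simulated genes were drawn independently of each other, so these runs do not test the preset correlation on lists of correlated genes.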

Results

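Gene expression was measured in mouse embryonic stem (ES) cells, the cultured pluripotent cells of the early embryo, kept undifferentiated or differentiated for 3 days with retinoic acid, the vitamin A derivative that activates the retinoic acid receptors. RNA of 3 biological samples per group was hybridised to 1-colour Cy3 arrays, with 2 technical arrays for each of the 6 samples, 12 arrays in all. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples. Median net intensities of the 41174 probes ran from 37.4 to 96.6 between arrays, background limits from 8.50 to 51.6, and the share of probes above the limit from 53.8% to 85.0%. The small numbers of samples and arrays limit the precision. The series is named for acetylation of histone H4 at lysine 16 during differentiation, and the comparison asks which transcripts differ between the 2 states.

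After retinoic acid most of the pluripotency genes tested fell, and many genes of the retinoic acid pathway and of the Hox clusters rose. Cyp26a1, which encodes an enzyme that breaks down retinoic acid, went from 6.67 ± 0.24 (SD, n = 3) to 14.71 ± 0.17 (SD, n = 3) in log2 intensity, a rise of 8.04 ± 0.18 (SE); it was above background on 4 of 6 undifferentiated arrays and over an intensity of 40000, near the top of the scale, on 2 arrays, so its size is approximate. Nr0b1 (Dax1), a nuclear receptor of the pluripotency network, fell by 6.34 ± 0.16 (SE), from 13.31 ± 0.16 (SD, n = 3) to 6.97 ± 0.08 (SD, n = 3). In the limma fit both had an adjusted p of 1.18e-06. Of the 15326 genes tested, 2872 (18.7%) were higher and 2083 (13.6%) lower after retinoic acid at an adjusted p under 0.05, and 1573 and 972 of these differed at least 2-fold. An unadjusted p under 0.05 was reached by 6554 genes, and in 7137 genes the 3 values of one group did not overlap those of the other, where chance gives 10%. The split between higher and lower depended on the scaling: higher genes made up 58.0% of the calls with quantile normalization, 48.1% (2440 higher and 2637 lower) when each array was scaled to its 75th percentile, and 51.4% (2372 and 2243) when scaled to its median. Of the calls of at least 2-fold, 61.8% were higher with quantile normalization, 52.7% (1399 higher and 1255 lower) with 75th percentile and 55.6% (1477 and 1179) with median scaling. These scalings moved the median log2 fold change of all genes from 0.0035 to -0.087 and -0.061. Lower genes numbered 1326 without retinoic acid replicate 1 and 1228 without retinoic acid replicate 3.

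**Figure D1:**
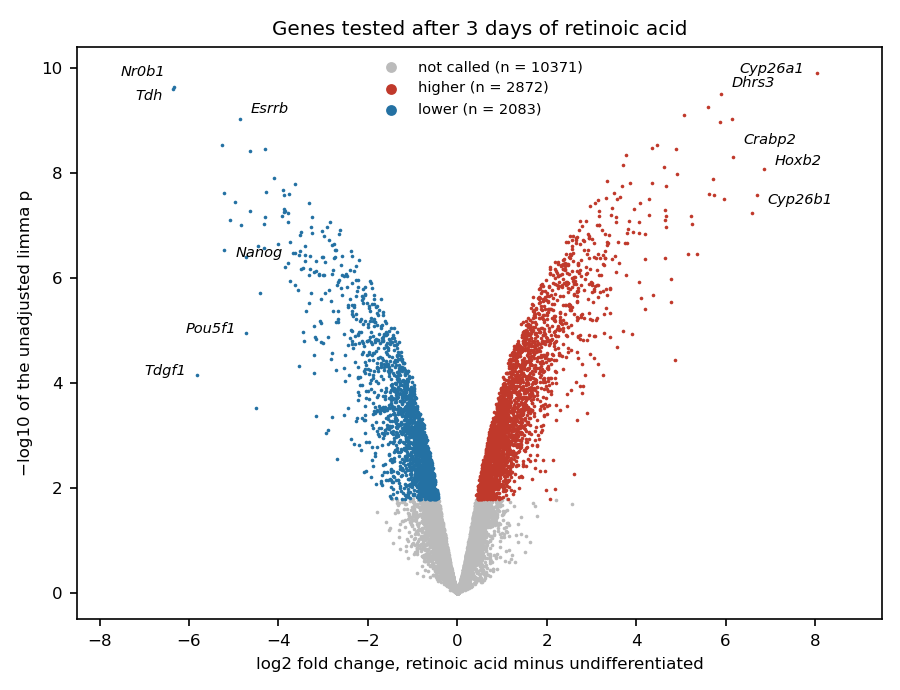
Each point is one of the 15326 genes tested, with its log2 fold change (retinoic acid minus undifferentiated) on the x axis and -log10 of the unadjusted limma p on the y axis, coloured by the call at an adjusted p under 0.05. The 2872 higher genes reach a change of 8.04 (Cyp26a1) and the 2083 lower genes a change of -6.36 (Tdh).

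Among the 10 largest rises of genes with regular symbols and groups that did not overlap were those of Cyp26a1, Hoxb2 (6.86), Cyp26b1 (6.70), Pmp22 (6.58), Crabp2 (6.17), Tshz1 (6.14), Dhrs3 (5.89), Gas1 (5.87) and Nr2f2 (5.75), and the 10 had adjusted p from 1.18e-06 to 1.53e-05. Of the undifferentiated arrays, 1 of 6 was above background for Hoxb2, 2 for Cyp26b1 and 3 for Nr2f2, so these sizes and their order are approximate too. The same holds for genes named further on, with 2 of 6 undifferentiated arrays above background for Foxc1, Foxc2, Zic1 and Sp5, 3 for Hoxb6, Meox1, Dkk1, Cdh2 and Zeb2, and 4 for Sox17 and Col1a2, and with 1 of 6 retinoic acid arrays for Foxd3, 3 for Spry4 and 5 for Elavl3 and Lefty2. Pmp22 encodes a myelin protein and Nr2f2 the nuclear receptor COUP-TFII. The 10 largest falls were those of Tdh (-6.36), Nr0b1, Tdgf1 (-5.83), Morc1 (-5.26), Khdc3 (-5.23), Jam2 (-5.21), Tcl1 (-5.08), Stmn2 (-4.97), Esrrb (-4.86) and Triml1 (-4.84), with adjusted p from 1.18e-06 to 0.000962. Tdh is threonine dehydrogenase, an enzyme abundant in mouse ES cells, and Tdgf1 is the Nodal co-receptor Cripto. For 7 of the 20 genes a second, dimmer probe moved the same way by at least 2-fold less: its change was 0.64 for Hoxb2, 3.37 for Tshz1, 4.38 for Dhrs3, -3.29 for Jam2, -1.39 for Stmn2, -0.59 for Esrrb and -1.67 for Triml1.

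Nearly the whole list of core and naive pluripotency genes fell. Of its 28 tested members 24 fell, Lin28a rose and 3 were not called, with the same numbers when adjusted over the list alone. The median change was -3.25 (limma's camera, adjusted p = 1.2e-18), and the call held with an estimated correlation (adjusted p = 0.042). The transcription factor Pou5f1 (Oct4) fell (-4.72 ± 0.48, SE), as did Nanog (-3.67 ± 0.23, SE), Sox2 (-3.05 ± 0.25, SE) and Zfp42 or Rex1 (-4.09 ± 0.17, SE; over an intensity of 40000 on 2 arrays, so approximate). All 6 retinoic acid arrays were above background for these 4 genes, with Nanog at 9.95 ± 0.33 (SD, n = 3) in log2 intensity against 13.62 ± 0.32 (SD, n = 3). The probe of Nanog carries no symbol on the array and was named from its description. The change of Lin28a was 0.63, and its call was lost in 10 alternatives. Among these were the fits without any 1 of 5 samples (all but retinoic acid replicate 2) and the other scalings (0.29 and 0.32). Klf2 fell by 3.85 on its brighter probe and differed by 0.03 on a second one.

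**Figure D2:**
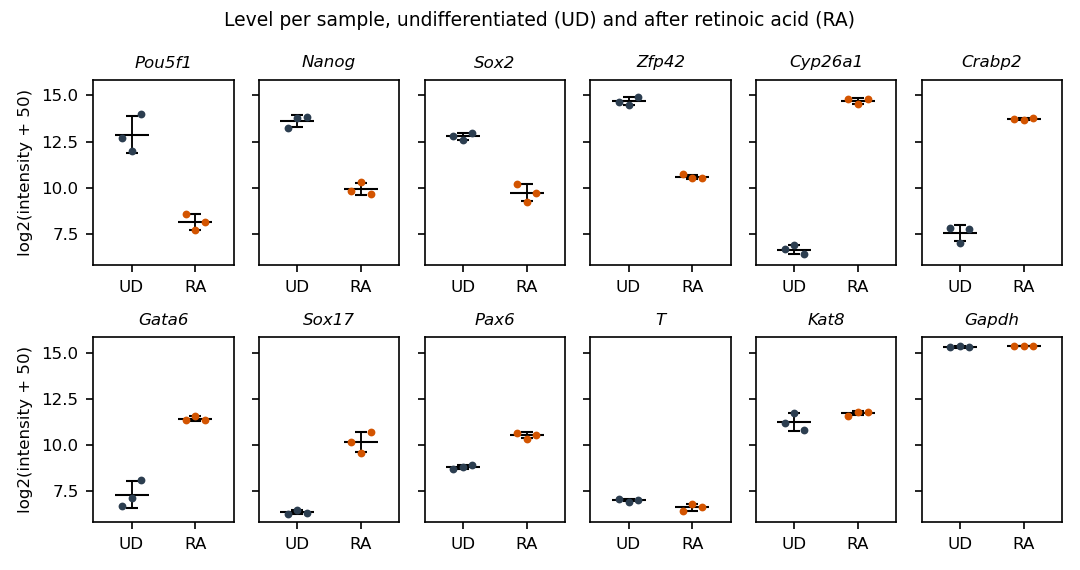
Points are the 6 biological samples (mean of 2 technical arrays), in log2(intensity + 50), for 12 genes in undifferentiated cells (UD) and after retinoic acid (RA); the bars show the mean and SD of 3 samples. Pou5f1, Nanog, Sox2 and Zfp42 are lower in every retinoic acid sample, Cyp26a1, Crabp2, Gata6, Sox17 and Pax6 are higher in every one, and T, Kat8 and Gapdh were not called.

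Genes of retinoic acid synthesis, binding, breakdown and response rose as a group. Of 26 tested, 17 rose, Bhlhe40 fell and 8 were not called (18 rose and 1 fell when adjusted over the list alone). The median change was 1.64 (camera, adjusted p = 8.8e-08), and the call was lost with an estimated correlation (adjusted p = 0.111 with an estimated correlation). Beside Cyp26a1 and Cyp26b1, the largest rise was that of Crabp2, which carries retinoic acid to its receptors, from 7.54 ± 0.43 (SD, n = 3) to 13.71 ± 0.04 (SD, n = 3). Of the receptors, Rxra rose by 1.38 (-0.05 on a second probe), while Rara (0.23), Rarg (-0.90) and Rarb (-0.27) were not called. The 2 probes of Rarb, a direct target gene of the receptors, moved apart: the bright one was at 12.40 and 12.14 in the undifferentiated and retinoic acid groups, and the dim one at 5.90 and 6.83. On the bright probe Rarb was called lower with 75th percentile scaling (-0.63). The fall of Bhlhe40 (-0.70) was lost without retinoic acid replicate 1 or 3.

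The Hox genes, which pattern the body axis, rose in all 4 clusters. Of 32 tested, 24 rose, 0 fell and 8 were not called (25 rose when adjusted over the list alone). The median change was 2.62 (camera, adjusted p = 1.6e-13), and the call was lost with an estimated correlation (adjusted p = 0.082 with an estimated correlation). Rises were called in 6 of 8 Hoxa, 9 of 10 Hoxb, 3 of 7 Hoxc and 6 of 7 Hoxd genes. These counts rest on the brightest probe of each gene. Hoxa3 was not called (0.40), but its second probe differed by 2.67. Hoxd3, above background on 0 of 6 undifferentiated arrays, was called higher. Its log2 difference of 1.01 includes the added 50 and is not a measured fold change. Its second probe differed by -0.47. Both probes were dim (mean intensities 27.3 and 24.1), so neither value carries much weight. Hoxa4 rose by 3.30, and its second probe differed by 1.26. Hoxb2 went from 5.92 ± 0.14 (SD, n = 3), above background on 1 of 6 arrays, to 12.78 ± 0.54 (SD, n = 3). Hoxb6 rose by 5.64, but by 0.31 on a second probe, which was not called. Hoxb1, the neighbour of Hoxb2, was at 9.91 ± 1.21 (SD, n = 3) and 9.42 ± 1.10 (SD, n = 3) and was not called. Its values in replicates 1, 2 and 3 were 10.79, 8.53 and 10.40 undifferentiated and 10.35, 8.20 and 9.72 after retinoic acid. Much of its SD thus followed the replicate number in both groups. In 4 of the 32 genes no array of one group was above background, and 4 were above it on all 6 undifferentiated arrays, too few to test the list with only genes above background on all 12 arrays. With the genes at background in one group at their bounds the median was also 2.62. It was 4.30 with 1 in place of 50 added before log2, and 1.75 with no filter on dim probes, with the call kept. Genes near background in undifferentiated cells could hardly be called lower, so the 0 falls carry little weight.

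**Figure D3:**
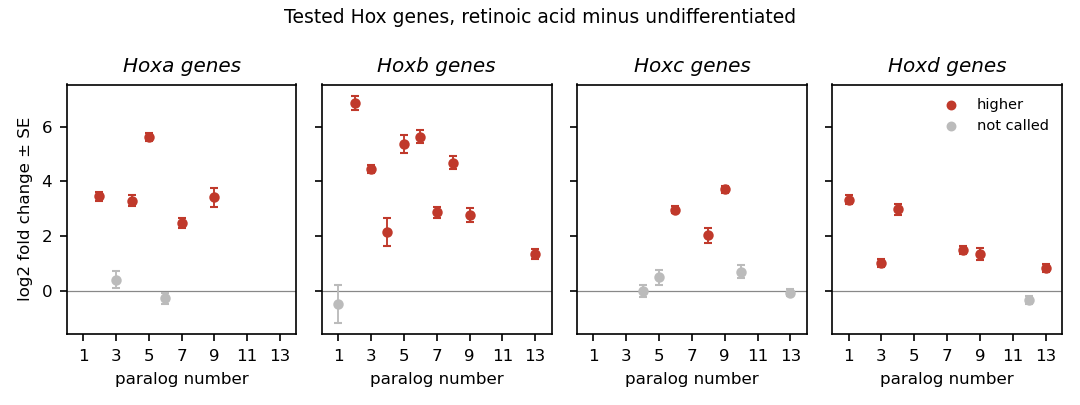
Points give the log2 fold change (retinoic acid minus undifferentiated, ± SE of the limma fit, 3 against 3 samples) of tested Hox genes (not every one of the 32 is drawn) against the paralog number, one panel per cluster; red genes were called higher and grey ones not called. Higher calls were made in 9 of 10 Hoxb but 3 of 7 Hoxc genes, a difference that was not tested.

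Among lineage markers, trophoblast, feeder fibroblast, mesoderm and endoderm lists rose, each through part of its members. Of 14 tested trophoblast markers 10 rose, Tfap2c fell (-3.08) and 3 were not called (10 rose and 2 fell when adjusted over the list alone), with a median of 2.45 (camera, adjusted p = 8.5e-05; adjusted p = 0.27 with an estimated correlation; median 1.58 with no filter on dim probes). Among the largest rises were those of the keratins Krt19 (5.15), Krt18 (4.78; over an intensity of 40000 on 2 arrays, so approximate) and Krt8 (4.65), which simple epithelia also express, while Eomes, a trophoblast stem cell factor, was not called (-0.47). Of 22 endoderm markers 10 rose, Lama1 fell and 11 were not called (11 and 1 over the list alone), with a median of 0.30 (camera, adjusted p = 0.019; adjusted p = 0.13 with an estimated correlation). The endoderm factors Gata6 (4.11 ± 0.34, SE; 1.51 on a second probe) and Sox17 (3.78 ± 0.27, SE) rose, as did Plat (4.09; 2.91 on a second probe), whereas Gata4 (-0.35), Foxa2 (-0.17) and Afp (-0.41) were not called. The endoderm median ran from 0.09 with no filter on dim probes to 0.75 with 1 added before log2. The endoderm call was lost without undifferentiated replicate 2 (adjusted p = 0.076) and when only genes above background on all 12 arrays were tested (adjusted p = 0.059). The fall of Lama1 (-0.52) was lost in 16 alternatives, among them each of the 6 fits without 1 sample.

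Of 16 primitive streak and mesoderm markers 7 rose, 0 fell and 9 were not called (8 rose when adjusted over the list alone), with a median of 0.45 (camera, adjusted p = 0.0036; adjusted p = 0.11 with an estimated correlation). Foxc2 (3.44), Foxc1 (3.18) and Meox1 (2.84) rose, transcription factors of paraxial mesoderm that other tissues also use, and T (Brachyury), the streak factor, was not called (-0.38 ± 0.16, SE), except with only technical array 1 (-0.63; limma, adjusted p = 0.0241). The median was 0.97 with 1 added before log2 and 0.29 with no filter on dim probes. With only genes above background on all 12 arrays, the median was -0.08 and the call was lost (adjusted p = 0.97). Of 15 markers of feeder fibroblasts, cells on which ES cells can be grown, 10 rose, Thy1 fell (-2.07; -0.76 on a second probe) and 4 were not called, with the same numbers over the list alone and a median of 1.10 (camera, adjusted p = 0.0021; adjusted p = 0.13 with an estimated correlation). Tagln (5.25), Col1a2 (3.38) and Pdgfrb (2.47) rose most, and 10 of the 15 genes were above background on all 6 undifferentiated arrays. With the filter on all 12 arrays the fibroblast median was 0.93 and the call was lost (camera, adjusted p = 0.18), and with 1 added the median was 1.68.

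Neither the neural nor the epiblast list was called. Of 26 neural genes 4 rose, 4 fell and 18 were not called (4 and 3 over the list alone; camera, adjusted p = 0.996), and the median (-0.06) differed in sign from the mean and the test. Zic1 (3.08), Msx1 (3.07) and Pax6 (1.71 ± 0.16, SE) rose, although second probes of Msx1 (-0.53) and Pax6 (-0.25) went the other way. Nes, the neural progenitor filament, was not called (-0.35), Stmn2 and Elavl3 (-1.61) fell, and Neurod1, above background on 0 of 6 retinoic acid arrays, was at least 2.44-fold lower. The call of Neurod1 was lost without retinoic acid replicate 1 or 3. Of 13 epiblast genes 5 rose, 4 fell and 4 were not called, with the same numbers over the list alone (median -0.13, mean 0.19; camera, adjusted p = 0.996). Cldn6 (2.68) and Cdh2 (2.60; 0.42 on a second probe) rose, whereas Etv4 (-3.25), Foxd3 (-2.44) and Dnmt3b (-1.80) fell. Sox4 (2.60) was called higher, but not in 4 of the 6 fits without 1 sample.

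Imprinted genes, expressed from one parental copy, rose together. Of 19 tested 13 rose, Snrpn fell and 5 were not called (14 and 1 over the list alone), with a median of 1.47 (camera, adjusted p = 1.6e-05; adjusted p = 0.078 with an estimated correlation). H19 rose by 4.89 ± 0.17 (SE), Peg3 by 4.64 ± 0.24 (SE) and Nnat by 4.38 ± 0.35 (SE). Igf2, which neighbours H19, was not called on its bright probe (14.24 and 14.32), while a second probe of the same accession went from 7.15 to 13.29. The fall of Snrpn (-0.88) was lost without retinoic acid replicate 1, 2 or 3.

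**Figure D4:**
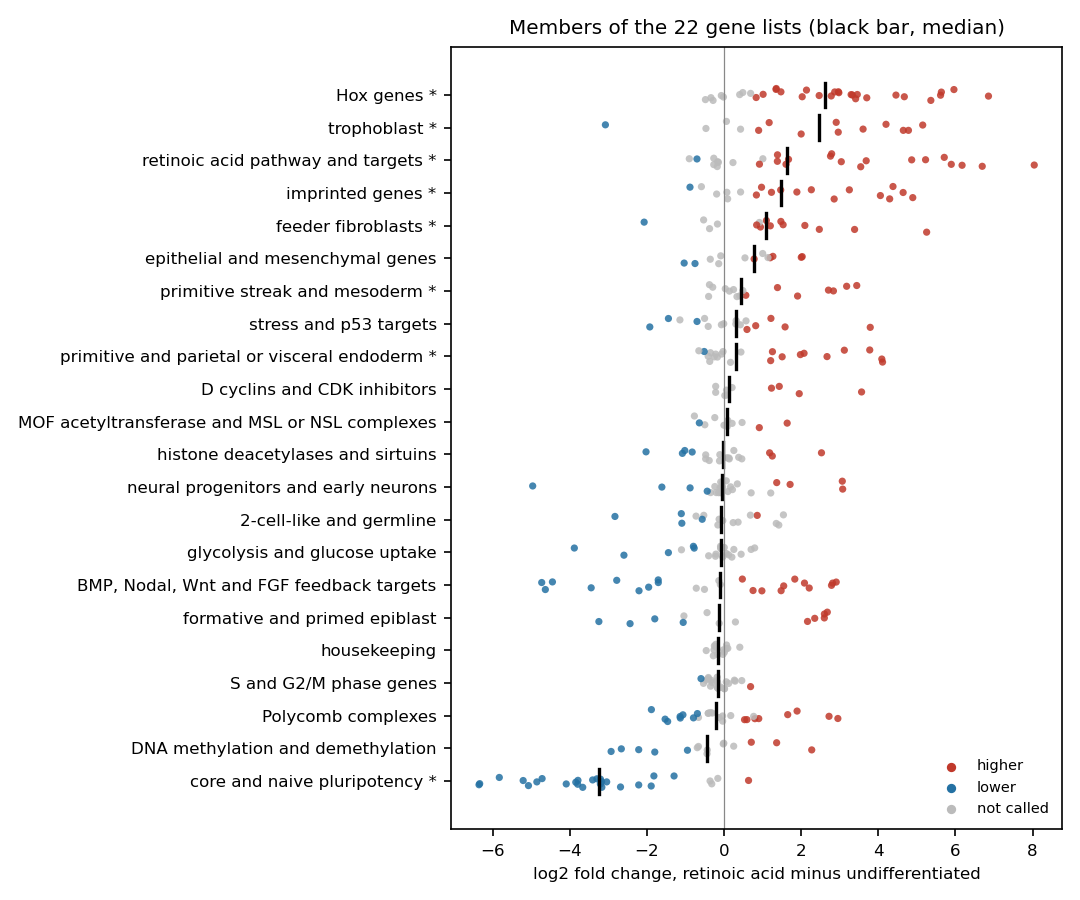
Each point is a tested member of one of the 22 gene lists, placed at its log2 fold change (retinoic acid minus undifferentiated) and coloured by its call; black bars are list medians, vertical scatter within a row has no meaning, and asterisks mark an adjusted camera p under 0.05. Medians run from -3.25 for pluripotency genes to 2.62 for Hox genes.

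Genes of H4K16 acetylation and of histone deacetylation moved both ways. Of 11 tested members of the complexes around the acetyltransferase MOF, 2 rose, 1 fell and 8 were not called, with the same numbers over the list alone (median 0.08, mean 0.11, test downward; camera, adjusted p = 0.996). Kat8, which encodes MOF, was at 11.25 ± 0.48 (SD, n = 3) and 11.72 ± 0.11 (SD, n = 3), a difference of 0.47 ± 0.24 (SE; limma, adjusted p = 0.19) that was called without undifferentiated replicate 2 (0.72, adjusted p = 0.021). It was 0.25 without undifferentiated replicate 3 (adjusted p = 0.428), and 0.18 and 0.21 with 75th percentile and median scaling. Msl3 of the MSL complex rose by 1.64 ± 0.18 (SE, with 0.45 on a second probe, not called), and Msl1 was higher by 0.91 ± 0.27 (SE). The call of Msl1 was lost in 7 alternatives, among them the fits without undifferentiated replicate 1 or 2 or retinoic acid replicate 1 or 3. Kansl1 of the NSL complex was not called (0.21), Phf20 fell (-0.64, lost without retinoic acid replicate 1 or 3), and Msl2 was not analysed here. Of 18 histone deacetylases and sirtuins, enzymes that remove acetyl groups, 3 rose, 4 fell and 11 were not called (4 and 4 over the list alone; camera, adjusted p = 0.86). Sirt1 (-2.02 ± 0.23, SE), Sirt3 (-1.08) and Hdac4 (-1.02) fell, while Hdac7 (2.53; 0.73 on a second probe, not called), Hdac9 (1.25; -0.01 on a second probe) and Sirt2 (1.18) rose. The call of Sirt3 was lost without retinoic acid replicate 1 or 3.

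Polycomb and DNA methylation genes moved both ways. Of 26 Polycomb genes 8 rose, 8 fell and 10 were not called (9 and 8 over the list alone; camera, adjusted p = 0.60; median -0.22 and mean 0.03). Phc2 (2.72) and Bmi1 (1.89; 0.74 on a second probe, not called) of the first Polycomb complex were among those that rose, whereas Phc1 (-1.89) of the same complex and Jarid2 (-1.53) and Eed (-1.46; -0.18 on a second probe) of the second fell. Of 15 DNA methylation genes 3 rose, 5 fell and 7 were not called (3 and 6 over the list alone; camera, adjusted p = 0.15; median -0.44), and the list was called lower with second brightest probes (median -0.64, adjusted p = 0.0415). Zfp57, which protects methylation at imprinted genes, fell (-2.93 ± 0.56, SE), as did Tet1 (-2.67 ± 0.25, SE) and Dnmt3l (-2.21 ± 0.32, SE), and Tet3 (2.27; -0.06 on a second probe) and Mbd2 (0.71) were among those that rose. The call of Mbd2 was lost in 4 alternatives, among them the fits without undifferentiated replicate 1 or retinoic acid replicate 2 or 3.

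Signalling targets split into rises and falls. Of 24 genes of BMP, Nodal, Wnt and FGF feedback 11 rose, 9 fell and 4 were not called (11 and 10 over the list alone; camera, adjusted p = 0.51; median -0.12). The Nodal targets Lefty1 (-4.73 ± 0.31, SE) and Lefty2 (-4.45 ± 0.27, SE) and the FGF feedback gene Spry4 (-4.64; -0.61 on a second probe) fell. The BMP target Id2 (2.91) and the Wnt targets Sp5 (2.81) and Dkk1 (2.79; 1.18 on a second probe) rose. Of 13 epithelial and mesenchymal genes 5 rose, 2 fell and 6 were not called (6 and 2 over the list alone; camera, adjusted p = 0.28; median 0.78). Zeb2 (2.03; 0.59 on a second probe), Cldn3 (2.002) and Snai2 (1.27, lost without undifferentiated replicate 1) rose. Itga6 fell (-1.04), and Cdh11 fell on its bright probe (-0.75, lost without undifferentiated replicate 1 or retinoic acid replicate 1 or 3) and rose on a second one (1.002).

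Most proliferation, housekeeping and glycolysis genes tested were not called. Of 24 S and G2/M phase genes Mki67 rose (0.69), Mcm3 fell (-0.60) and 22 were not called (0 and 0 over the list alone; camera, adjusted p = 0.26; median -0.17), and both calls were lost without either retinoic acid replicate 1 or 3, among others. The list was called lower with 75th percentile scaling (median -0.54, adjusted p = 0.00608) and with median scaling (median -0.50, adjusted p = 0.00934). Of 10 D cyclins and CDK inhibitors 4 rose, Ccnd2 (3.57), Cdkn2b (1.95) and Cdkn2c (1.43) most, 0 fell and 6 were not called, with the same numbers over the list alone (camera, adjusted p = 0.12; median 0.14), and the list was called without undifferentiated replicate 3 (adjusted p = 0.036) and with second brightest probes (adjusted p = 0.0415). None of 15 housekeeping genes was called by limma, over all genes or the list alone (camera, adjusted p = 0.51; median -0.17), although a second probe of B2m (-0.25) differed by 2.41. With 75th percentile scaling the housekeeping list was called lower (median -0.37, adjusted p = 0.0419). Gapdh differed by 0.06 ± 0.13 (SE; over an intensity of 40000 on 8 arrays, near the top of the scale), Actb by -0.17 ± 0.50 (SE) and Tbp by -0.28 ± 0.15 (SE). Actb in replicates 1, 2 and 3 was at 11.59, 10.49 and 12.35 undifferentiated and 11.46, 10.56 and 11.91 after retinoic acid. Much of its spread thus followed the replicate number in both groups. Of 21 glycolysis genes 5 fell, 0 rose and 16 were not called, with the same numbers over the list alone (camera, adjusted p = 0.10; median -0.09). Pfkp (-3.88), Pdk1 (-2.60) and Hk2 (-1.45) fell most, and the list was called lower without undifferentiated replicate 2 (adjusted p = 0.036), with 75th percentile scaling (median -0.63, adjusted p = 0.0025) and with median scaling (median -0.59, adjusted p = 0.0026).

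Neither the stress list nor the germline list was called. Of 17 stress and p53 targets 5 rose, 3 fell and 9 were not called, with the same numbers over the list alone (camera, adjusted p = 0.60; median 0.30, from 0.006 without retinoic acid replicate 1 to 0.56 without retinoic acid replicate 2). Atf3 (3.79), Ccng1 (1.58) and Hspa1a (1.22) rose, and Trib3 (-1.93), Pmaip1 (-1.44) and Asns (-0.70) fell. The call of Asns was lost in 10 alternatives, among them the fits without retinoic acid replicate 1, 2 or 3 or undifferentiated replicate 2 or 3. Of 16 genes of 2-cell-like cells and the germline Ddx4 rose (0.86), 4 fell and 11 were not called (1 and 5 over the list alone; camera, adjusted p = 0.51; median -0.08). Sycp3 (-2.83), Piwil2 (-1.11) and Tex19.1 (-1.10) fell most. The call of Tex19.1 was lost in 6 alternatives, among them the fits without undifferentiated replicate 1 or 3 or retinoic acid replicate 2 or 3.

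Lists were also tested with limma's fry, which asks only whether the genes of a list move on balance one way and does not compare them with other genes. Of the lists that camera did not call, it gave an adjusted p of 0.000159 for BMP, Nodal, Wnt and FGF feedback, 0.000611 for DNA methylation, 0.000939 for glycolysis, 0.00316 for epithelial and mesenchymal genes, 0.0131 for D cyclins and CDK inhibitors, 0.0233 for stress and 0.0236 for neural genes. Among the lists that camera did not call, only the DNA methylation and the epithelial and mesenchymal medians stayed within 1.5 times when 1 sample was left out, and those of the neural, MOF, deacetylase, signalling and germline lists changed sign. The lists that camera called also had a fry adjusted p under 0.05.

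Technical arrays of a sample were much closer to each other than the samples of a group were. The median SD over genes was 0.044 on the log2 scale between technical arrays, 0.26 between the 3 undifferentiated samples and 0.17 between the 3 retinoic acid samples. Over the 15326 genes tested, the correlation across genes was 0.992 to 0.999 between technical arrays, 0.960 to 0.990 between samples of a group and 0.889 to 0.920 between samples of different groups. Genes are not independent replicates in these correlations.

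Control spots of the DCP series were dimmer on the arrays of replicate 1 (array medians 766 to 902) than on those of replicate 2 (2442 to 2595) and replicate 3 (3013 to 3312), in both groups. Within the 3 replicate numbers, 99.9% of the called genes had the sign of the fit each time. These genes were called from the same samples, which nearly fixes this share, so it does not measure consistency between replicates. Over all genes tested, the numbers at least 2-fold higher were 2023, 1413 and 2099 and lower 1303, 1173 and 1455. The median change of pluripotency genes was -3.32, -3.31 and -3.68 within replicates 1, 2 and 3, that of Hox genes 2.95, 2.27 and 2.47, that of retinoic acid genes 2.12, 1.48 and 1.72, that of imprinted genes 1.97, 1.19 and 1.68 and that of trophoblast markers 2.152, 2.195 and 2.203. Fibroblast markers gave 1.37, 0.90 and 1.40, mesoderm markers 0.50, 0.42 and 0.60 and endoderm markers 0.16, 0.54 and 0.50.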

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

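The settings with 1 or 10 added, without the array of doubtful header and with the second brightest probe were chosen after the data were examined. Of 2409 values of named genes under the settings, 95 lost the call, 3 gained one and 7 changed sign with a call in the main fit or the setting. The other 2304 kept their side of the threshold. Among them are sign changes of genes called in neither fit, such as Actb (-0.66 to 0.27 without 1 sample). With an adjusted p under 0.01 the counts were 1784 genes higher and 1114 lower, from the stricter threshold itself. Each probe by itself gave 1474 probes at least 2-fold lower, over 26587 probes. In all other settings that keep the 6 samples the 4 counts stayed within 1.5 times. Without 1 sample, lower genes ran from 1228 (without retinoic acid replicate 3) to 2108, with 1326 without retinoic acid replicate 1. Each of these fits leaves out 1 sample, so the smaller number of samples alone does not account for the lowest counts. The cause was not tested. With only genes above background on all 12 arrays, which removes genes silent in one group, the medians were 0.17 for endoderm, -0.079 for mesoderm and 0.93 for fibroblast markers and their calls were lost, and the Hox list had under 5 genes and was not tested. With 1 added the medians of Hox (4.30), fibroblast (1.68), mesoderm (0.97) and endoderm markers (0.75) were over 1.5 times those with 50, and with no filter those of trophoblast (1.58), mesoderm (0.29) and endoderm (0.09) were lower by as much, with the calls kept. The endoderm median was also 0.58 with 10 added, 0.59 with the mean of probes, and 0.19 and 0.49 with either technical array alone, and the mesoderm median 0.82 with 10 added. Without 1 sample the endoderm median ran from 0.24 to 0.38, and its call was lost without undifferentiated replicate 2. With an estimated correlation the medians (retinoic acid genes 1.64, Hox 2.62, endoderm 0.30, trophoblast 2.45, mesoderm 0.45, fibroblasts 1.10, imprinted 1.47) are those of the main test and the calls were lost. The 7 sign changes that involve a call were those of Cdh11 with the mean of probes (0.38), and with the second brightest probe of Cdh11 (1.002), Msx1 (-0.53), Tet3 (-0.063), Pax6 (-0.25), Hdac9 (-0.0078) and Rarb (0.94). The cause was not tested at single genes. With the replicate block 2849 genes were higher and 2040 lower. The deviations of same-numbered samples correlated at -0.060, 0.22 and 0.066, and 1 of the 3 undifferentiated samples (replicate 2) correlated best with its own number. These few correlations cannot exclude a batch shared by same-numbered samples, since the DCP control spots differed by replicate number in both groups. Hoxb1 and Actb also varied alike by replicate number in both groups, a pattern picked out after the values were seen. The main fit was planned without such a block, and the labels state no pairs. Background correction from mean signals, mean signal without correction and the slide as a block were not run, since the files hold no such columns. Signal over background limits the dim genes: on the array with the fewest, 53.8% of probes were above the limit.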

Other observations

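The gene families described first, the neighbour pairs over 100 kb apart, the probe pairs with 1 added, and the tests of the brighter probe, of the scaling and of the Hox paralog number were chosen after the results were seen, and the criteria of the brighter-probe and Hox tests were also revised after their first outcomes were known. Families sharing a symbol stem and at least 10 tested genes were compared with all tested genes (166 stems, Fisher's exact test, one-sided, Benjamini-Hochberg over both directions). This test treats genes as independent, which genes of a family or a cluster need not be. Its p-values may therefore be too small and do not measure the spread between samples. Beside Hoxb, 3 families stood out among the rises. Of 37 collagen (Col) genes 20 rose and 4 fell (adjusted p = 0.000389), among them Col1a2 (3.38), Col4a2 (3.12) and Col4a1 (2.67), of which Col4a1 and Col4a2 form basement membranes. Of these 37 genes 5 are on the fibroblast list, which rose too, and 4 of them rose, as did 16 of the other 32. Of the Col genes that rose, only Col4a1, Col4a2, Col11a1, Col5a1, Col18a1 and Col22a1 were above background on all 6 undifferentiated arrays. The others were above it on 1 (Col12a1, Col6a1 and Col14a1) to 5 of them (Col26a1, Col16a1 and Col8a2), so their sizes are approximate. Of 18 tetraspanins (Tspan) 12 rose and 2 fell (adjusted p = 0.00122), led by Tspan18 (3.02, above background on 2 of 6 undifferentiated arrays) and Tspan12 (2.93, on 5 of 6). Of 11 Wnt ligand genes 7 rose and 0 fell (Fisher's exact test, adjusted p = 0.048, with 6 rising under either other scaling), Wnt9a (2.61) and Wnt6 (1.95) most. Of these 7, only Wnt6 was above background on all 6 undifferentiated arrays. The undifferentiated means of the others lay near background, from 5.92 (Wnt2, above it on 1 of 6 arrays) to 6.76 (Wnt9a, on 4 of 6).

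Among the falls the Klf, Mrpl, Snhg, Wdr and Ddx families stood out. Of 17 Klf genes 10 fell and 0 rose (adjusted p = 0.00136), including Klf9 (-3.20), Klf8 (-2.65) and Klf3 (-2.10) beside the pluripotency members Klf2, Klf4 and Klf5. Of 49 genes of the large mitochondrial ribosomal subunit (Mrpl) 17 fell and 1 rose (adjusted p = 0.00804), with 28 and 25 falling when arrays were scaled to the 75th percentile or the median. Of 11 snoRNA host genes (Snhg) 7 fell, led by Snhg1 (-1.62), and 0 rose (1 rose with either other scaling; adjusted p = 0.00804). Of 59 Wdr genes 20 fell and 4 rose (adjusted p = 0.00387), and of 37 DEAD-box helicase (Ddx) genes 13 fell and 1 rose (adjusted p = 0.032). Of 49 genes with the stem Rpl, most of them cytoplasmic ribosomal proteins, 1 fell (Rpl39l, -2.53; 4 and 3 fell with the other scalings) and 0 rose.

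Neighbouring genes changed together. Over 14895 pairs of adjacent tested genes the log2 fold changes correlated at 0.14, against -0.016 to 0.016 in the central 95% of 1000 shuffled gene orders. Cross-hybridisation between tandem paralogs is argued against as the whole cause, since the correlation was 0.106 without pairs that share a symbol stem or the first 3 letters, and so is shared sequence of overlapping genes, since it was 0.105 without overlapping pairs as well (shuffled orders up to 0.027). Pairs over 100 kb apart gave 0.047, above the central 95% of shuffled orders (up to 0.036) but below the highest of them (0.057). Regulation shared by neighbours in differentiation, as a hypothesis, may remain, and no test here separates it from other causes of linked expression.

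Some probes of one gene disagreed. In 331 of 6226 genes with 2 measured probes (5.32%) the changes of the brightest and the second probe differed at least 2-fold at an adjusted p under 0.05 (limma), in 116 of them with opposite signs, and over all 6226 genes the 2 changes correlated at 0.78. Disagreement was rarer where both probes had an intensity of at least 500 (1.42% against 6.85%; Fisher's exact test, p = 8.95e-22), which is consistent with dim probes that cannot follow a gene, although the added 50 favours this outcome (1.08% against 4.32% with 1 added; p = 3.15e-12), and more common where the 2 probes carry different accessions (6.6% against 4.82%; p = 0.00659), which is consistent with different transcripts. A brighter probe that also reads other transcripts is left undecided. Over the 331 genes the brighter probe changed less in 19.6% (65 genes; exact 95% interval 15.5% to 24.3%), which by the first criterion counted against it, but the added 50 shrinks the changes of dim probes and so tilts that share. The criterion was therefore restricted to the 25 disagreeing genes with both probes at 500 or more, where the brighter probe changed less in 15 (60%; exact 95% interval 38.7% to 78.9%), as in Igf2 (0.07 and 6.14) and B2m (-0.25 and 2.41), but not in Klf2 (-3.85 and 0.03) or Pax6 (1.71 and -0.25).

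More genes rose than fell with quantile normalization (58.0% of calls), but part of the excess may come from the normalization, since higher genes were 48.1% of calls with 75th percentile and 51.4% with median scaling. For calls of at least 2-fold (61.8% higher) this stays open, with 52.7% and 55.6%. The value added before log2 is argued against, with 58.8% when 1 was added in place of 50. No biological explanation of the excess was tested.

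A candidate explanation for the different rises of Hox genes is their paralog number, anterior genes rising more. Spearman's rho across the 32 genes, which are not independent replicates, was -0.293 (permutation p = 0.103, two-sided, 100000 permutations), so the test leaves it undecided. By the criterion first written, under which a p of 0.05 or more counted against it, paralog number would have been rejected; that criterion was replaced because a p that misses the threshold does not exclude a trend. The median change was 3.30 for 15 genes of paralogs 1 to 5 and 2.03 for 17 genes of paralogs 6 to 13, and rho was -0.43 in the Hoxa, -0.13 in the Hoxb, 0 in the Hoxc and -0.75 in the Hoxd cluster.

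The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, gave 2872 genes higher and 2083 lower, and 1573 and 972 at least 2-fold. The highest count of any other split was 0 in limma for each of the 4 counts, with up to 672 genes at an unadjusted p under 0.05. Each other split mixes retinoic acid and undifferentiated samples, so the difference between these groups adds to the spread that the fit measures. The counts of 0 are therefore no measure of chance.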
